A study of Mus musculus with 6 samples.

How the data were processed

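The series holds 6 RNA sequencing libraries of splenic germinal centre B cells, 3 labelled DN and 3 labelled DP, all with the same batch label. Per the labels' protocols, spleen suspensions were stained and sorted by flow cytometry, and stranded polyadenylated RNA libraries were made with a KC-Digital kit from 2 ug of total RNA. The deposited values are read counts per gene, not normalized, with 1 table per library. Per the submitters' processing notes, the tools were Trim Galore 0.6.6, STAR 2.7.10a and HTSeq 0.13.5 with the mm10 build of the mouse genome; the notes as used here give no roles or settings. The annotation release, the strand setting of the counting and the handling of any molecular identifiers are not given in the sources used here. If reads were counted without regard to strand, reads of a gene and its antisense partner would be merged, and if identifiers were not used, duplicate reads would make counting intervals too narrow.

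Each deposited table listed 55401 genes and 5 summary rows that name no gene. The summary rows held 12.6% of all counts on average in DN and 9.56% in DP and were left out of library sizes and tests. Gene symbols came from the deposited tables, and 217 genes shared their symbol with another. Gene types, positions, transcript lengths and GC content came from GENCODE release M21 for mm10, to which 55141 gene identifiers matched without and 54349 with their version.

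Libraries were grouped by their titles. The comparison was DP against DN with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter (minimum count 10), robust estimation, no block and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The filter left 11296 genes; the 44105 genes below it held 0.113% of the counts. Standard errors were computed from the fitted log2 fold change and its F statistic. CPM were computed from deposited counts with TMM-adjusted library sizes. TMM factors lay between 1.069 and 1.071 in DN and between 0.926 and 0.941 in DP. The 46 gene lists were fixed before the data were examined, and the 41 with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation and fry beside it. Counts of changed genes in a list are given with the adjustment over all tested genes and with that over the list alone. Shares of counts were compared with an exact two-sided permutation test of 3 against 3, whose smallest p is 0.1.

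Genes named in the text followed a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out antigen receptor segments, pseudogenes and unnamed gene models. It also took up to 4 members with the smallest p of each described list, the surface antigen list whatever its result, and Bcl6, Cxcr4, Cd83, Cd86, Myc, Prdm1, Ccr6, Bach2, Foxo1 and 1 more. A few genes the rule took are not reported here. Beyond the rule, Ncl was named from the composition check and Alas2 as an abundant erythroid marker, both after their values were seen.

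Libraries of a group were compared in pairs before they were averaged. Over genes with at least 20 counts in a pair, chi-square per degree of freedom was 1.98 to 3.26 within DN and 1.96 to 3.24 within DP, against 144 to 182 between groups. Every pair within a group thus differed by more than sampling noise and all 6 libraries were kept.

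The test was tried on simulated data for this comparison. Counts were drawn for the 11296 tested genes from the real means and library sizes, with 200 genes changed, 50 at each fold. The filter then left 11140 of the simulated genes. edgeR recovered 8%, 56%, 82% and 92% of changes of 1.1-fold, 1.2-fold, 1.5-fold and 2-fold, and 4.8% of its calls were not simulated as changed. Every simulated gene had the same dispersion and a mean taken over both groups, and a far smaller share of genes changed than in the real comparison. These rates therefore need not hold for the real data. Alternatives were DESeq2 size factors, upper-quartile factors and library totals alone, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, estimation without robust weights, an adjusted p of 0.01, a minimum fold of 1.5, immunoglobulin genes left out, the replicate number as a block, and each library or pair of same-numbered libraries left out. Thinning DP libraries to the mean DN depth, leaving out the 10 most abundant genes and removing trends with GC content and transcript length were added after the data were seen.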

Results

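Polyadenylated RNA was sequenced from splenic germinal centre B cells of wild-type C57BL/6 mice. The mice had received sheep red blood cells, a T-dependent antigen, into the peritoneal cavity. They were challenged with the same cells on day 5 and killed on day 12. The sorted cells fell into 2 subsets that the labels call DN and DP, and each subset was represented by 3 libraries. The labels do not say which markers the names stand for. Counts assigned to genes ranged from 8904415 to 11897360 per library in DN and from 17509384 to 20538024 in DP, so that DP libraries were 1.88 times deeper on average. A floor of 3 counts corresponded to 0.236 to 0.315 normalised counts (CPM) in DN libraries and to 0.155 to 0.183 CPM in DP libraries, which covers counting error only. The design text speaks of 3 mice that each gave both subsets, but no label ties a library to a mouse. Immunoglobulin V segment usage and the correlation of same-numbered libraries did not show separate animals, and other values were not checked for this. The p-values below therefore measure only the spread between these libraries, which may be technical. Unless stated otherwise, levels are mean CPM ± SD over n = 3 libraries, and changes are log2 fold changes of DP against DN ± standard error.

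The series asks how the transcriptome of germinal centre B cells differs between the DN and DP subsets. Tnfrsf8, which encodes the CD30 receptor, rose from 0.226 ± 0.236 CPM in DN to 41.0 ± 1.14 CPM in DP (7.31 ± 0.19 on the log2 scale, edgeR adjusted p = 2.35e-40). The DN libraries held 6, 0 and 2 of its counts, a mean below their floor, and the DP libraries 2157 together, a ratio of 164 with a 95% exact counting interval of 83.2 to 381. Without DN replicate 1 its log2 change was 8.51. Ccnd2, the cell cycle regulator cyclin D2, rose from 1.96 ± 0.202 to 68.9 ± 0.416 CPM (5.14 ± 0.11), and Fabp5, a fatty acid binding protein, rose from 10.7 ± 0.410 to 139 ± 3.61 CPM (3.70 ± 0.07). On the DN side, Ifit1bl1, a member of the interferon-induced Ifit family, fell from 101 ± 4.70 to 2.72 ± 0.335 CPM in DP (-5.21 ± 0.09, adjusted p = 1.60e-50), and Trp53inp1, a p53-induced gene, fell from 62.0 ± 2.87 to 2.51 ± 0.414 CPM (-4.61 ± 0.10).

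Of 11296 genes tested, 8571 (75.9%) passed an adjusted p of 0.05, with 4328 higher in DP and 4243 higher in DN. Of the changed genes, 66.9% differed by less than 2-fold. In all, 1386 genes were at least 2-fold higher in DP and 1448 at least 2-fold higher in DN. When the change was tested against a minimum of 1.5-fold, 3876 genes passed, 1964 of them higher in DP and 1912 higher in DN. The share of changed genes that were higher in DP was 50.5% with the composition factors used here and 38.0% with library totals alone, a scaling that moved the median gene by -0.20. The 3 DP libraries lay wholly above or below the 3 DN libraries for 77.0% of tested genes, where chance alone gives 10%. Within groups the libraries differed little, with a common biological coefficient of variation of 3.31%.

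Among called genes of at least 5 CPM in the higher group and with no overlap between groups, the 12 with the largest changes on the DP side included Socs3, an inhibitor of cytokine signalling (4.64 ± 0.27), the lysophospholipid transporter Mfsd2a (4.54 ± 0.25), the lysine methyltransferase Smyd2 (4.08 ± 0.12) and the folate carrier Slc19a1 (3.82 ± 0.21). Ankrd33b (4.04 ± 0.19), the peroxisomal reductase Pecr (3.76 ± 0.16), the actin nucleator Spire1 (3.73 ± 0.14) and the nucleotide hydrolase Dnph1 (3.72 ± 0.29) followed. Some of these changes rest on few DN counts, with 5, 3 and 3 for Socs3, 5, 6 and 3 for Mfsd2a and 3, 6 and 5 for Dnph1. Lad1, which encodes ladinin, had 2 counts in the 3 DN libraries together and 298 in DP, a ratio of 90.8 with a 95% exact counting interval of 24.9 to 753. The 12 such genes at the DN end included the stem cell receptor Lgr5 (-4.93 ± 0.31), the sodium channel genes Scn8a (-4.90 ± 0.21) and Scn11a (-4.43 ± 0.26), the actin-severing protein gelsolin, Gsn (-3.92 ± 0.09), and the cytokine receptor subunit Il5ra (-3.97 ± 0.24). Pafah1b3 (-4.28 ± 0.10), Adhfe1 (-3.97 ± 0.25) and Ccdc175 (-3.87 ± 0.20) fell as well. Hbb-bh1, an embryonic beta-like globin gene with close paralogues, fell by 4.70 ± 0.32 from 6.25 ± 1.74 CPM in DN. Sox5os3 (-4.98 ± 0.34, from 8 counts in DP) lies antisense within Sox5, which itself fell by 3.06 ± 0.11, and their reads cannot be separated with certainty because the strand setting of the counting was not given. In the mm10 build, Tnfrsf8 (ENSMUSG00000028602.12) lies on chromosome 4 from 145267137 to 145315164, Ccnd2 (ENSMUSG00000000184.12) on chromosome 6 from 127125162 to 127152193, Ifit1bl1 (ENSMUSG00000079339.7) on chromosome 19 from 34592891 to 34601956 and Trp53inp1 (ENSMUSG00000028211.11) on chromosome 4 from 11156431 to 11174379. All 4 are annotated as protein-coding genes, and their counts are sums over exons as the deposited files give them.

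**Figure D1:**
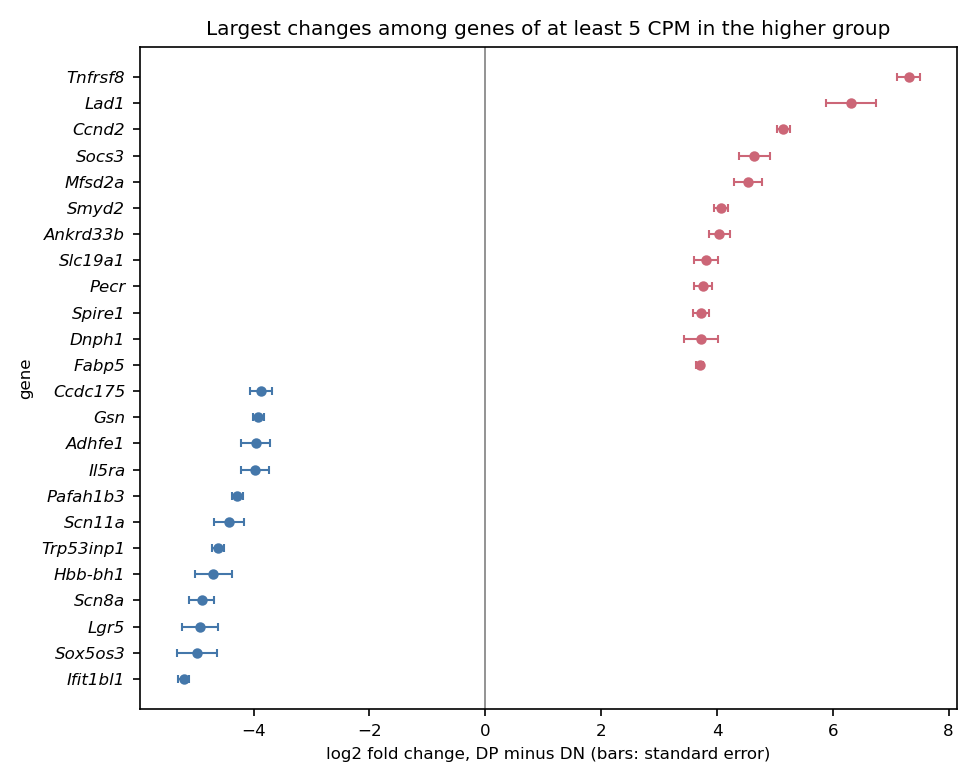
Log2 fold change of DP against DN (x axis) for the 12 genes with the largest rise and the 12 with the largest fall (y axis) among called genes of at least 5 CPM in the higher group and with no overlap between groups; points are fitted values and bars the standard error over 3 libraries per group. Tnfrsf8 at 7.31 and Ifit1bl1 at -5.21 mark the ends among these.

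Genes that define the germinal centre state were mostly lower in DP. The transcriptional repressor Bach2 fell from 319 ± 1.71 to 33.3 ± 2.13 CPM (-3.26 ± 0.05), and Bcl6, the master regulator of the germinal centre B cell, from 160 ± 1.94 to 76.6 ± 1.09 CPM (-1.06 ± 0.04). Cxcr4, the chemokine receptor that draws cells to the dark zone, fell by 1.93 ± 0.09 and Foxo1, a transcription factor of that zone, by 1.20 ± 0.06. Against this, Myc rose from 5.32 ± 0.323 to 62.0 ± 0.628 CPM (3.55 ± 0.09), Batf rose by 3.64 ± 0.07 and Irf4 rose by 2.54 ± 0.07. Irf4 encodes a transcription factor required for plasma cell formation. Myc (ENSMUSG00000022346.16) lies on chromosome 15 from 61985391 to 61990374.

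In the list of dark zone genes, 11 of 17 tested fell in DP and 3 rose, with 11 and 3 adjusted over the list alone. The nuclear GTPase Nuggc (-2.50 ± 0.04), Gcsam (-1.89 ± 0.04) and Rassf6 (-1.89 ± 0.04) were among them. The dark zone median was -1.04 and the camera adjusted p was 0.00145 (adjusted p = 0.114 with an estimated correlation). Of 25 germinal centre identity genes, 18 fell and 5 rose, as they did adjusted over the list alone, with a median of -0.83. Neil1, a DNA glycosylase, fell by 2.79 ± 0.05. The camera adjusted p for that list was 3.36e-04 (adjusted p = 0.0999 with an estimated correlation). Nuggc and Gcsam belong to both lists. Among 23 light zone genes, 14 rose and 4 fell, also adjusted over the list alone. The NF-kB inhibitor Nfkbia rose by 1.99 ± 0.07 beside Myc, Batf and Irf4. The antigens Cd83 and Cd86 of this list moved apart, as Cd83 rose by 0.84 ± 0.05 and Cd86 fell by 0.97 ± 0.05. Cd72 fell by 0.61 ± 0.04. The light zone median was 0.43 and the camera adjusted p was 0.0411 (adjusted p = 0.182 with an estimated correlation). Without DN replicate 2 the camera adjusted p was 0.0574. With library totals alone 12 light zone genes rose and 7 fell, and the median was 0.24.

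**Figure D2:**
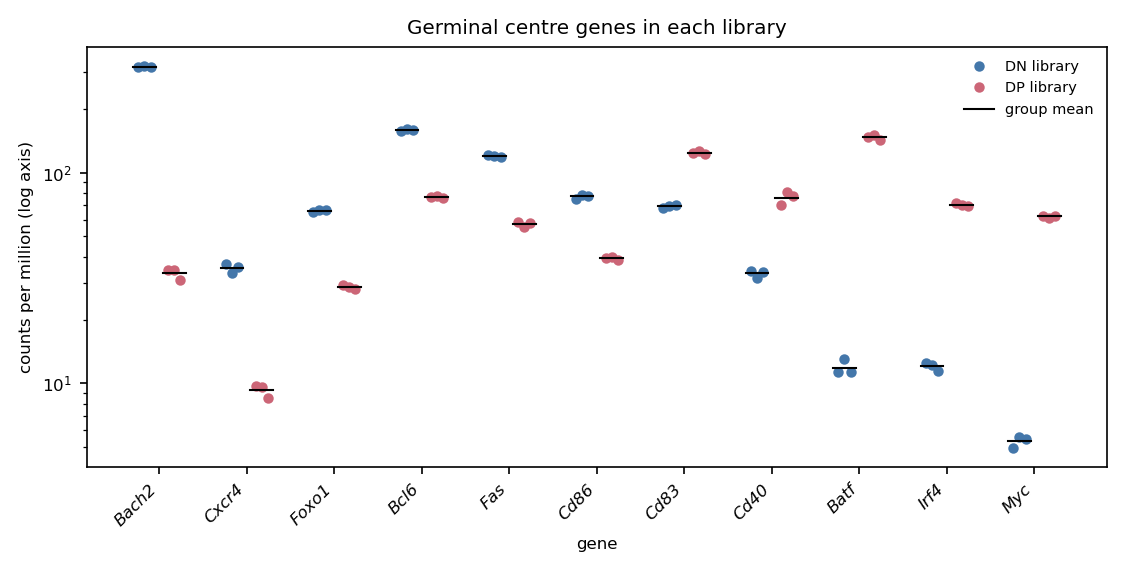
CPM (log axis) of germinal centre genes in each of the 3 DN and 3 DP libraries, with black bars at the group means. Bach2, at 319 CPM in DN and 33.3 CPM in DP, and Myc, at 5.32 and 62.0 CPM, moved in opposite directions with no overlap between the groups.

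Genes of ribosome production and of protein and energy metabolism were mostly higher in DP. All 35 tested genes of the list of MYC-linked ribosome biogenesis rose, also adjusted over the list alone, and 34 of them rose at least 2-fold. The median was 2.10. The mitochondrial chaperone Hspd1 rose from 372 to 2250.1 CPM (2.60 ± 0.04), the nucleolar protein Nolc1 from 229 to 1408 CPM (2.62 ± 0.04) and Mybbp1a by 2.45 ± 0.04. Its camera adjusted p was 1.93e-15 (adjusted p = 0.0696 with an estimated correlation). Ncl, which encodes nucleolin and belongs to this list, took 0.519% ± 0.00892 of gene counts in DN and 2.02% ± 0.0958 in DP (SD, n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Of 44 cytosolic ribosomal protein genes, 38 rose and 2 fell (39 and 2 adjusted over the list alone), by a median of only 0.30, with Rps2 at 1.40 ± 0.04 and Rpl38 at 1.29 ± 0.05. That list had a camera adjusted p of 4.14e-05 (adjusted p = 0.446 with an estimated correlation), and near-identical processed copies of these genes make single values uncertain. With library totals alone 25 rose and 8 fell, with a median of 0.10.

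In glycolysis, 19 of 21 genes rose and 2 fell, also adjusted over the list alone, with a median of 0.92. Hk2, the first enzyme of the pathway, rose from 23.1 to 134 CPM (2.54 ± 0.06), lactate dehydrogenase Ldha by 1.69 ± 0.04 and the lactate transporter Slc16a1 by 2.11 ± 0.06. Glycolysis had a camera adjusted p of 7.71e-05 (adjusted p = 0.22 with an estimated correlation). Of 40 nuclear genes of oxidative phosphorylation, 26 rose and 4 fell, also adjusted over the list alone, with a smaller median of 0.35. Cytochrome c, Cycs, rose by 1.21 ± 0.04 and Atp5b by 0.72 ± 0.03 (camera adjusted p = 0.00277; adjusted p = 0.194 with an estimated correlation). Here 22 rose and 10 fell with library totals alone, and the median was then 0.15. The unfolded protein response list, which holds chaperones of the endoplasmic reticulum, had 17 of 22 genes higher in DP and 3 lower, also adjusted over the list alone. Hspa5 rose from 378 to 1199 CPM (1.67 ± 0.04), Pdia4 by 1.72 ± 0.04 and Hyou1 by 1.69 ± 0.04. The median of these genes was 0.77 and the camera adjusted p was 3.93e-04 (adjusted p = 0.0999 with an estimated correlation). Of 19 dissociation stress genes, many of them cytosolic chaperones, 11 rose and 6 fell, also adjusted over the list alone. Their median was 0.70, and their summed level was 14075 CPM in DN and 37778 CPM in DP. Hsp90ab1 rose from 7004 to 20989 CPM (1.58 ± 0.03), Hsph1 by 1.75 ± 0.04 and Junb by 1.39 ± 0.09, while Fos fell by 0.94 ± 0.13. The list did not pass (camera adjusted p = 0.138; adjusted p = 0.244 with an estimated correlation), and 10 of its genes rose and 7 fell with library totals alone, where the median was 0.50. Mitochondrially encoded genes took 1.23% ± 0.0257 of gene counts in DN and 0.941% ± 0.0228 in DP (SD, n = 3, exact two-sided permutation p = 0.1). These shares are of counts without TMM factors. With those factors 4 of 11 tested genes rose and 3 fell, with a median of 0.17. The median was 0.45 with the GC and length trend removed and -0.026 with library totals alone.

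Genes that respond to NF-kB and CD40, the receptor for T cell help, were mostly higher in DP, while components of B cell receptor signalling were mostly lower. Of 26 NF-kB and CD40 response genes, 20 rose and 6 fell, also adjusted over the list alone, with a median of 0.82. Nfkb2 rose from 45.2 to 191 CPM (2.07 ± 0.05) and the survival gene Bcl2a1d by 2.96 ± 0.11, whereas the death receptor gene Fas fell by 1.07 ± 0.05. The camera adjusted p was 0.00411 (adjusted p = 0.18 with an estimated correlation). Of 30 B cell receptor signalling genes, 26 fell and 1 rose, also adjusted over the list alone, with a median of -0.63. The receptor chain Cd79b fell from 296 to 83.7 CPM (-1.82 ± 0.04), the complement receptor Cr2 by 2.56 ± 0.05 and the kinase gene Lyn by 1.24 ± 0.04. For receptor signalling the camera adjusted p was 5.23e-07 (adjusted p = 0.107 with an estimated correlation). Of 8 heavy chain constant region genes, 7 fell and 1 rose, also adjusted over the list alone, with a median of -0.61. Ighg1 went from 1999 to 1384 CPM, Ighm from 813 to 555 CPM, and Ighg2c fell by 1.15 ± 0.06 (camera adjusted p = 0.0108; adjusted p = 0.18 with an estimated correlation). In MHC class II presentation, 14 of 17 genes fell and 2 rose, also adjusted over the list alone, and the median was -0.34. The ubiquitin ligase gene Marchf1, whose product removes MHC class II from the surface, fell by 3.19 ± 0.06, and H2-Ob fell by 1.99 ± 0.04. The lysosomal reductase gene Ifi30 rose by 1.00 ± 0.05. MHC class II presentation had a camera adjusted p of 0.00548 (adjusted p = 0.225 with an estimated correlation), and its median was -0.53 with library totals alone.

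Genes of the interferon response, of quiescence and of naive and memory B cells were mostly lower in DP. Of 30 type I interferon response genes, 27 fell and 1 rose, also adjusted over the list alone, with a median of -1.21. Ifit3 fell from 72.6 to 9.67 CPM (-2.90 ± 0.07), Ifi27l2a from 93.5 to 14.0 CPM (-2.73 ± 0.07), Ifi213 by 2.30 ± 0.07 and the regulator Irf7 by 1.52 ± 0.05. Interferon response genes had a camera adjusted p of 3.59e-08 (adjusted p = 0.0696 with an estimated correlation). Among 17 genes of quiescence and cell cycle brakes, 14 fell and 1 rose, also adjusted over the list alone, with a median of -1.13. Btg1 fell by 2.41 ± 0.05, Ccng2 by 2.46 ± 0.07 and Txnip by 1.87 ± 0.07 (camera adjusted p = 3.43e-04; adjusted p = 0.0999 with an estimated correlation). The follicular naive B cell list had 16 of 21 genes lower and 3 higher in DP, also adjusted over the list alone, with a median of -1.20. Foxp1 fell by 2.42 ± 0.06 and Bank1 by 1.20 ± 0.04, and Btg1 and Txnip stand in this list too (camera adjusted p = 3.43e-04; adjusted p = 0.199 with an estimated correlation). Of 26 memory B cell and precursor genes, 16 fell and 7 rose (17 and 7 adjusted over the list alone), with a median of -1.01. Vim fell by 2.38 ± 0.05 and Pecam1 by 2.51 ± 0.08. That list had a camera adjusted p of 0.0249 (adjusted p = 0.18 with an estimated correlation). Of 27 receptors and regulators of migration and positioning, 20 fell and 5 rose, also adjusted over the list alone, with a median of -0.82. The integrin Itga4 fell by 1.76 ± 0.06 and Rgs2 by 1.87 ± 0.07 (camera adjusted p = 9.97e-04; adjusted p = 0.0999 with an estimated correlation).

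Markers of other cell types moved with these groups. Of 9 erythroid genes, 8 fell in DP and 1 rose, also adjusted over the list alone, with a median of -1.80. Slc4a1 went from 16.2 ± 1.24 to 4.91 ± 0.622 CPM and Hbb-bs from 11.4 ± 1.11 to 2.61 ± 0.346 CPM. The gene that rose was Tfrc, a transferrin receptor that dividing B cells use as well (camera adjusted p = 0.0263; adjusted p = 0.181 with an estimated correlation). Of 15 macrophage and monocyte genes, 11 fell and 1 rose, also adjusted over the list alone, with a median of -0.83. Lyz2 went from 6.15 ± 0.940 to 1.91 ± 0.329 CPM and Cd5l from 7.92 ± 0.438 to 3.14 ± 0.771 CPM (camera adjusted p = 0.0282; adjusted p = 0.244 with an estimated correlation). Of the naive cell genes, Ighd was at 9.78 ± 1.16 CPM in DN and 2.92 ± 0.0967 CPM in DP, and Bank1 at 273 ± 4.80 and 119 ± 3.42 CPM.

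Of 36 tested genes for surface antigens that are used to sort germinal centre B cells, 20 were lower in DP and 11 higher, also adjusted over the list alone, with a median of -0.52. Complement receptor Cr2, Cd55 (-2.85 ± 0.14), Cd93 (-2.97 ± 0.33), Ighd (-1.74 ± 0.16), Efnb1 (-1.20 ± 0.06), Cd200 (-1.18 ± 0.17) and Nt5e (-1.06 ± 0.08) fell together with Cxcr4 and Fas. Smaller falls were seen for Cd86 (-0.97 ± 0.05), a costimulatory ligand that is in the light zone list as well. Cd180 (-0.95 ± 0.05), Cd44 (-0.76 ± 0.05), Ptprc (-0.71 ± 0.03) and Cd72 (-0.61 ± 0.04) also fell. So did Ighm (-0.55 ± 0.03), Spn (-0.52 ± 0.05) and Cd22 (-0.22 ± 0.04). Pdcd1lg2 fell by 0.78 ± 0.33, with an adjusted p of 0.029, but by only 0.28 without DN replicate 1 (adjusted p = 0.545). Its call was also lost without DP replicate 2 (0.112) or DP replicate 3 (0.0683), with DESeq2 (0.113), limma-voom (0.0594) or no filter (0.075), and after thinning (0.0673). Among antigens higher in DP were the endocytic receptor Ly75 (1.57 ± 0.05), Tfrc (1.31 ± 0.05), Cd40 (1.19 ± 0.06), the light zone antigen Cd83 (0.84 ± 0.05), the adhesion molecules Icam1 (0.68 ± 0.05) and Itgb1 (0.42 ± 0.05), Fcer2a (0.41 ± 0.05) and Sdc1 (1.77 ± 0.40). Sdc1 was near the floor in DN, at 0.468 ± 0.291 CPM from 2, 7 and 5 counts, and at 1.51 ± 0.159 CPM in DP. Cd80 rose by 0.68 ± 0.25 (adjusted p = 0.0136), a call lost without DN replicate 1 (adjusted p = 0.064), with library totals alone (0.0794), with DESeq2 (0.0578) and after thinning (0.128). Slamf1 (0.17 ± 0.05) and Cd24a (0.08 ± 0.04) passed as well, but with library totals alone Slamf1 stood at -0.02 (adjusted p = 0.725) and Cd24a was called in the opposite direction at -0.11 (adjusted p = 0.00414). Slamf1 also missed the threshold after thinning (adjusted p = 0.0729). Cd24a missed it without DN replicate 1, DN replicate 3, DP replicate 1 or DP replicate 2 (adjusted p of 0.151, 0.0972, 0.0602 and 0.0613), with DESeq2 size factors (0.054), upper-quartile factors (0.232), DESeq2 (0.0872) or the stricter filter (0.0581), and without immunoglobulin genes (0.0861). The changes of Itgb1, Fcer2a and Cd22 were 0.23, 0.22 and -0.41 with library totals alone, and with the GC and length trend removed that of Ptprc was -0.47. Cd9 (0.38 ± 0.39), Cd38 (-0.12 ± 0.20), Cd69 (-0.22 ± 0.12), Ly6d (-0.34 ± 0.27) and Ccr6 (-0.39 ± 0.27) did not pass, and Cd1d1 and Cd5 were below the expression filter. Prdm1, which drives plasma cell differentiation, rose by 1.47 ± 0.26 from 1.26 ± 0.424 CPM. The camera adjusted p of the antigen list was 0.0379 (adjusted p = 0.18 with an estimated correlation), and 0.0782 when immunoglobulin genes were left out.

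**Figure D3:**
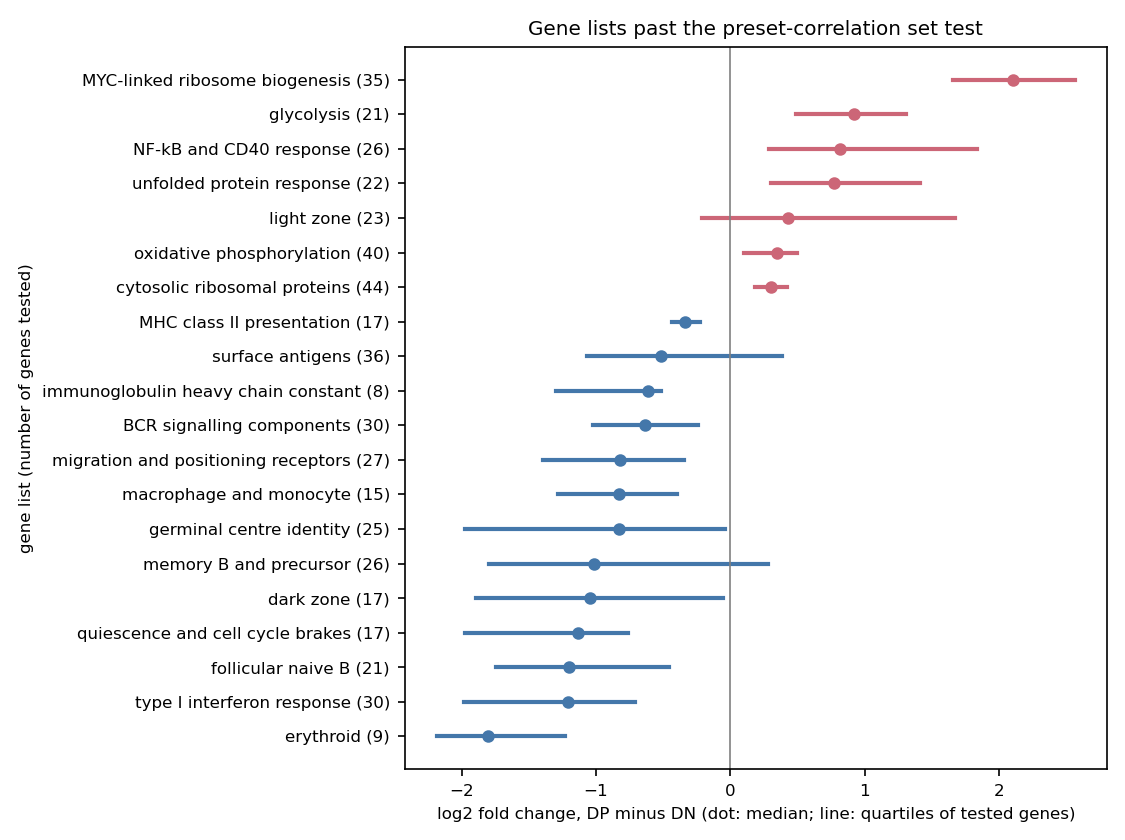
Median log2 fold change of DP against DN (dots) with quartiles (lines) over the tested genes of the 20 gene lists that passed the camera test with a preset correlation; the number of genes tested stands beside each name. Medians run from -1.80 for the erythroid list to 2.10 for MYC-linked ribosome biogenesis.

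Of 41 lists tested, 20 passed with the preset correlation of 0.01, 7 towards DP and 13 towards DN, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.0696 and 10 lists had an unadjusted p under 0.05. By fry, which asks only whether a list's genes move one way on balance, 39 passed. In the 9 other splits of the 6 libraries into groups of 3, all of which mix the subsets, 7 to 17 lists passed with the preset correlation. Those splits keep part of the DP and DN difference, so their calls do not measure chance alone. These lists were fixed before the data were examined and share members, so that they are not independent of one another. With library totals alone the memory, surface antigen, macrophage and erythroid lists missed the threshold (adjusted p of 0.093, 0.0835, 0.0651 and 0.0835).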

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

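The comparison of reads outside any annotated feature was chosen after their share was seen. These reads, 1 of the kinds that the counting gave to no gene, entered no comparison of expression, yet their share differed between groups. They made up 6.88% ± 0.355 (SD, n = 3) of all counted reads in DN and 4.13% ± 0.104 in DP, with no overlap (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).

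The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. By edgeR, the DP and DN split gave 8571 changed genes and 2834 changed at least 2-fold, and it was the only 1 of the 10 splits to reach either count. The highest other split gave 0 for both, with 13 to 32 genes at an unadjusted p under 0.05 in the other splits and 0 changed by limma-voom. For the gene lists, the real split gave 20 called lists with the preset correlation, again the only 1 of the 10 to do so, but the others gave 7 to 17. Calls of lists with a preset correlation thus also arose in splits that mixed DN with DP libraries. Each such split kept part of the DP and DN difference between its groups and put the rest within them. Its 0 changed genes and its called lists therefore do not show what chance alone would give.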

How the results depend on the processing

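The thinning of DP libraries, the removal of the 10 most abundant genes, the GC and length correction and, for the lists, upper-quartile factors and library totals were chosen after the data were seen. The count of 8571 changed genes lay between 7777 and 9102 under all alternatives except a minimum fold of 1.5, which gave 3876 genes, 1964 higher in DP and 1912 higher in DN, by its own construction. Without 1 library it lay between 8251 and 8558, and without a pair of same-numbered libraries between 8053 and 8080. Thinning DP libraries to the mean DN depth, with fewer genes tested, gave 8036 genes, and 7931 of them were called in the same direction as before. The count of called lists was 0 with an estimated correlation and 39 by fry, a different test, and otherwise 16 to 22, with 20 to 22 without 1 library. Under fry 3 lists that camera did not call passed in the opposite direction, namely MHC class I presentation (adjusted p = 0.0288), hypoxia response (0.0103) and switching, hypermutation and DNA repair (6.75e-04); the cause was not tested. S phase passed without DP replicate 1 (adjusted p = 0.0491). With library totals alone, which moved the median gene by -0.20, the changes of Lck, Slamf1 and Cd24a turned to -0.0071, -0.022 and -0.11, and with the GC and length trend removed mt-Nd4 turned to 0.040. No other gene named by the rule changed direction among those called in the main or the alternative fit. Genes called in neither fit were not checked for direction. Some settings, such as those without a pair of same-numbered libraries, were not compared gene by gene. Cd69 and Ccr6 passed with library totals alone (adjusted p of 0.00159 and 0.0481), and Cd69 with upper-quartile factors (adjusted p = 0.04995). The replicate number as a block gave 8589 changed genes, 4338 higher in DP and 4251 higher in DN, and 20 lists. Deviations from the group means correlated at 0.0562, -0.00611 and -0.0182 between same-numbered libraries across genes, and only number 1 correlated best with its own number, so the libraries were taken to share only a number. Depth limits DN values more than DP values, and genes under the filter were not compared.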

Other observations

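The tests of V segment usage, of list medians under added settings and of other cell types were chosen after results were seen, and the test for naive B cells and the minimum count and marker set of 2 others were changed after a first result. Among lists that did not pass the set test, many single genes changed. In S phase, 20 of 33 genes were higher in DP and 6 lower (20 and 7 adjusted over the list alone), among them Cdca7 (0.90 ± 0.04) and the thymidylate synthase gene Tyms (0.98 ± 0.05) on the higher side and Slbp, the histone mRNA binding protein, on the lower (-0.51 ± 0.04). The median was 0.19, and -0.01 with library totals alone (camera adjusted p = 0.0664). In G2 and M phase, 19 of 36 genes fell and 10 rose, also adjusted over the list alone, and none by 2-fold: the kinetochore gene Ndc80 fell by 0.69 ± 0.04 and Ccnb1, cyclin B1, rose by 0.64 ± 0.04 (camera adjusted p = 0.283). The 4 tested histone genes, too few for a set test, all fell, with H2ax at -1.30 ± 0.06. In the plasma cell list, 12 of 22 genes rose and 6 fell, also adjusted over the list alone; the chaperone Hsp90b1 rose by 1.43 ± 0.04, while Slamf7 fell by 1.18 ± 0.04 (camera adjusted p = 0.283). Of 19 p53 response genes, 11 fell and 5 rose, also adjusted over the list alone, with Rrm2b, a ribonucleotide reductase subunit, at -1.91 ± 0.05 and the nuclease gene Aen going from 48.6 to 137 CPM (camera adjusted p = 0.125).

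Several receptor and signalling groups split in both directions. Of 31 receptors for T cell help and costimulation, 13 rose and 12 fell, also adjusted over the list alone; Icosl, the ligand of ICOS on T cells, fell from 39.2 to 3.35 CPM (-3.53 ± 0.11) and Btla by 1.04 ± 0.05, against Ly75 at 1.57 ± 0.05 (camera adjusted p = 0.953). That list had a median of 0.03, and -0.16 with library totals alone, while camera gave it the opposite sign. Of 22 apoptosis regulators, 11 fell and 8 rose, also adjusted over the list alone. The pro-apoptotic Bcl2l11 fell by 2.40 ± 0.11 and the anti-apoptotic Mcl1 by 0.96 ± 0.04, while the anti-apoptotic Bcl2a1d rose by 2.96 ± 0.11 (camera adjusted p = 0.523). Of 30 genes of switching, hypermutation and DNA repair, 12 rose and 11 fell, also adjusted over the list alone; the polymerase Polh fell by 1.49 ± 0.05 and the abasic site endonuclease Apex1 rose by 2.22 ± 0.05 (camera adjusted p = 0.965). In the atypical B cell list, 6 of 11 genes fell and 5 rose, also adjusted over the list alone, with Apoe at -2.60 ± 0.04 and Zbtb32 at 1.43 ± 0.11 (camera adjusted p = 0.578). Of 8 dendritic cell genes, 6 rose and 2 fell, also adjusted over the list alone; Zbtb46 had 0 counts in DN and 89 in DP, at least 18.1-fold higher against a floor of 3 counts over the DN group (camera adjusted p = 0.132). The median of that list was 0.55, also with Zbtb46 at its bound, and 0.35 with library totals alone. Of 24 chromatin regulators, 13 rose and 10 fell, also adjusted over the list alone, with Kmt2a at -1.72 ± 0.04 and Dnmt3a at 1.58 ± 0.08 (camera adjusted p = 0.467). Of 19 toll-like receptor pathway genes, 12 fell and 4 rose (13 and 4 adjusted over the list alone), with Tlr7 at 2.09 ± 0.16 (camera adjusted p = 0.0868). The other lists that did not pass are given as genes higher and lower in DP, with the same counts adjusted over the list alone and then the camera adjusted p. These were cholesterol synthesis with 9 and 5 of 22 (0.484), MHC class I presentation with 6 and 6 of 16 (0.965), hypoxia response with 6 and 5 of 15 (0.965), immediate early genes with 4 and 6 of 15 (0.556) and marginal zone B cells with 5 and 8 of 16 (0.576). Mitochondrially encoded genes had 4 and 3 of 11 (0.851), T follicular helper cells 3 and 4 of 7 (0.578), T cells 3 and 3 of 7 (0.849) and stromal cells 0 and 3 of 7 (0.176). With library totals alone more genes were lower than higher in S phase (13 and 12), T cell help (15 and 9), switching and repair (17 and 10), cholesterol synthesis (9 and 6), MHC class I (10 and 5), hypoxia response (7 and 6), T cells (4 and 2) and mitochondrially encoded genes (4 and 2). Too few genes for a set test were measured for neutrophils, with 0 higher and 3 lower of 3, light chain constant regions, with 0 and 3 of 4, NK cells, where Il2rb rose by 3.59 ± 0.21, and platelets, where Itgb3 fell by 1.43 ± 0.06.

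Immunoglobulin V segment usage hardly differed among the 3 libraries of a group: over 155 segments with at least 20 counts in each group, chi-square per degree of freedom was 1.43 in DN and 1.20 in DP. Other genes of like abundance gave medians of 1.44 and 1.22 over 200 draws. Chi-square per degree of freedom was 12.8 for summed DN against summed DP. That value rests on summed counts, with no draw of other genes beside it, so it cannot be set against those of single libraries. Shares of V segments correlated at 0.909 to 0.927 between DN and DP libraries. One shared source of cells or RNA per group may explain the small spread within groups, as a hypothesis. It asks for a ratio under 1.5 to genes of like abundance, and the higher ratio was 0.994, whereas private repertoires of separate mice would raise it. Whether same-numbered libraries carry 1 mouse's repertoire cannot be told apart from no pairing, because the spread within groups is so small: their mean correlation across segments was 0.0530, and another of the 6 pairings reached 0.0757. Mice with closely similar V usage stay possible and were not tested, and the design text names 3 mice.

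The ribosome biogenesis genes rose by a median of 2.10 on the log2 scale. The prediction for library scaling and the most abundant genes was a median under 1. The lowest over the other scalings and the removal of the 10 most abundant genes was 1.91. These settings moved the median gene by -0.20 at most, so a median under 1 was out of reach and the result decides nothing. A factor per library moves all genes alike, so it cannot open the gap between this list and other genes. That argues against scaling for the gap alone. The median of all tested genes was 0.0061, but TMM factors centre it by design, and it was -0.19 with library totals alone. After thinning the list median was 2.07, but thinning barely shifts ratios of abundant genes, so it could not test depth. GC content or transcript length are argued against, with 2.08 after the trend was removed. A difference between the DP and DN cells may thus underlie the pattern, as a hypothesis found and tested on the same data. RNA content per cell was not measured, so absolute levels stay open.

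The interferon response genes were lower in DP by a median of -1.21. A factor per library moves all genes alike, and the list median lay at -1.21 from the median of all tested genes. That distance argues against library scaling as the source of the gap to other genes, also as set by the most abundant genes. It stayed at -1.21 under each scaling and without the 10 most abundant genes. These re-runs act through such factors, which leave the distance unchanged, so they added no test. With the GC and length trend removed the list median was -1.34. Myeloid or erythroid cells in the DN gate would bring their abundant transcripts, yet of 56 markers of macrophages, neutrophils and erythroid cells those higher in DN summed to an excess of only 0.104 of the 894 CPM excess of the interferon list, and their net excess was 89.1 CPM without Tfrc, which dividing B cells use, and -10.4 CPM with it, with Lgmn, which B cells also express, at 91.9 CPM in DN and 78.2 CPM in DP and Alas2 at 18.8 and 5.40 CPM. Follicular naive B cells in the DN gate cannot be told apart from a change within germinal centre cells, because the members of their list that were higher in DN summed to 0.676 of the interferon excess (net excess of the list 576 CPM), while 6 markers picked from that list after a first result gave 0.0235 (net -1.82 CPM). Many genes of that list, such as Bank1 at 273 CPM in DN and 119 CPM in DP, are also used by germinal centre B cells, and of the markers Ighd was at 9.78 and 2.92 CPM, Klf2 at 1.52 and 0.678 CPM, Ccr7, untested, at 0.522 and 0.347 CPM, Cd38 hardly differed at 3.19 and 2.93 CPM, and Fcer2a went the other way, from 68.8 to 91.6 CPM. Different exposure of the DN and DP subsets to interferon may also account for the pattern, as an untested hypothesis.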
